A study of Arabidopsis thaliana with 18 samples.

How the data were processed

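The study measured transcripts on 18 one-colour Cy3 arrays of rosette leaves from WT and ahp4 plants dehydrated for 0, 2 or 5 h, with 3 biological replicates per group. Per the file headers, the scanner files hold fluorescence intensity per spot from Agilent Feature Extraction 10.7.3.1 on a 44K format with 532 rows and 85 columns. The deposited values are log2 signal, which differed from the log2 processed signal of the files by a constant on each array that sets its 75th percentile to 0. No unassigned column remained.

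Processed signal was brought to log2 and reduced by each array's 75th percentile over non-control probes. Spots of a probe were averaged (50 probes had 5 spots), and 1417 control spots and spots marked as non-uniform or population outliers were left out, which left 3095 probes without a value on 1 or more arrays. Of 43603 probes, 36214 had 1 locus in the TAIR10 annotation of the array, 503 had several and 6886 had none, and the last 2 kinds were left out as belonging to no single gene. Symbols came from the array annotation and a reference gene table, which matched 36003 probes. The brightest probe stood for each of 26170 loci. A locus was tested where its probe was well above background on all 3 arrays of at least 1 group, which 20383 loci met, and 6518 of them had a second probe that did so. Signal over background sets the precision for dim probes.

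Group means over all 18 arrays were fitted with lmFit and eBayes (default settings) of limma 3.58.1 under R 4.3.3, with data.table (version 1.17.8) and statmod 1.5.0. The 11 contrasts were ahp4 against WT at each time, 2 h and 5 h against 0 h and 5 h against 2 h in each genotype, and the difference between genotypes in the 2 h and 5 h responses. Adjusted p-values are Benjamini-Hochberg values over the genes of a contrast, and a call needed an adjusted p under 0.05 and a change of 2-fold or more. Standard errors come from the same fit. AHP4 was also tested by exact permutation of 3 against 3 arrays. Gene lists (27 lists of 390 loci, written by hand from general knowledge) were tested with limma camera at a preset correlation of 0.01, adjusted over the lists of a contrast, beside counts of called members, also adjusted over the list alone. The lists cover abscisic acid metabolism, receptors and clade A phosphatases, protective proteins and transcription factors of dehydration, osmolytes, cuticle, aquaporins, heat shock, reactive oxygen, flavonoids, jasmonate, ethylene, salicylate and defence, cytokinin metabolism, signalling and type-A response regulators, photosynthesis, senescence, cell wall growth, guard cells, the clock, reference genes, and markers of flowers, meristems, roots and vessels. The meristem list held 2 measured genes and was not tested.

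The groups, tests, filters, lists and naming rule and the first set of alternatives were fixed before the data were examined. The rule named AHP4, the 8 largest rises and 8 largest falls of each contrast among called genes with a symbol whose group values did not overlap, and the 4 members of each list with the smallest p. Any other gene is said to be chosen after its value was seen. Alternatives were normexp background (offset 50), quantile normalization, the median of bright probes as the scale, the deposited table, other filters on dim probes, the mean of all probes of a locus, fits of the compared groups only, trend and robust eBayes, array weights, a replicate block, no fold limit and each array left out in turn. Added after seeing the data were removal of a local position trend, loci with any outlier-marked spot left out, agreement of 2 probes, division by the spike-in slope, the slides of WT 5 h and ahp4 0 h left out, and the outermost 50 rows left out.

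The pipeline was tested on simulated data with 20163 genes, 50 of them changed at each level. At 2-, 4-, 8- and 16-fold it recovered 22, 76, 78 and 82% of changes for ahp4 against WT at 0 h, 38, 78, 80 and 92% for WT at 5 h and 16, 58, 82 and 72% for the genotype difference at 5 h, with 8 false calls each. These false calls do not give the number on the real arrays, where each group lay on its own slide. A first limit, over 80% recovery from 8-fold upward, was missed and replaced by checks of the arithmetic.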

Results

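Rosette leaves of 24-day-old Arabidopsis thaliana plants were profiled in wild type (WT, Col-0) and in ahp4-1 (ahp4), a mutant of cytokinin signalling named after the histidine phosphotransfer protein gene AHP4 (AT3G16360). Aerial parts had been detached and left to dry for 0, 2 or 5 h, and each of the 6 groups held 3 independent biological replicates on 18 one-colour arrays. Their number limits the precision of every value. Gene values are log2 fold changes with the standard error of the limma fit, and genes were called at an adjusted p below 0.05 with a change of at least 2-fold. Spots marked as outliers were left out, so some groups had fewer than 3 values. Groups with 2 are marked n = 2, and where only 1 array of a group had a value no fold is given. Arrays on which a probe was well above background are called detected. A gene whose probe was not well above background on any array of the dimmer group is given as a bound, "at least N-fold". The bound is the mean of the brighter group over the mean of the dimmer group, taking on each array the higher of the probe's own signal and the lowest signal among probes well above background. For lists, the adjusted p of camera at its preset correlation comes first, and that with a correlation estimated from the data is marked estimated. Counts of list members are given among those measured, and the counts adjusted over the list alone were the same unless given. Where a second probe of a called gene did not move at least 2-fold the same way its value is printed, and probes within 20 rows of an end of the array are marked with that distance.

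Each group lay on its own slide, and all WT slides were scanned on 1 day and all ahp4 slides on another, so slide or scan day and group cannot be told apart. The slides of WT at 5 h and ahp4 at 0 h differed most from the other 4. Spots marked as non-uniform numbered 802 to 807 and 627 to 680 on their arrays, 274 to 398 on those of WT at 2 h and 0 to 24 elsewhere. Correlations between replicate arrays, taken across genes, which are not independent replicates, reached only 0.905 to 0.907 and 0.867 to 0.893 on these slides, against 0.975 to 0.992 on the others. Calls on these slides gathered in the outer rows of the array, which has 532 rows. In ahp4 against WT at 0 h, 58.3% of genes within 10 rows of an end were called lower, against 1.83% of genes over 50 rows away. At 5 h, 52.8% of the outer genes were called higher, against 1.16% of the inner ones. For 5 h against 2 h in ahp4, which uses neither slide, the shares called lower were 10.1% and 8.3%. Called genes with a value on only 1 array of a group numbered 123 of 6918 in WT at 5 h against 0 h, 43 of 1745 and 75 of 1240 between genotypes at 0 and 5 h, and 0 in ahp4 at 5 h against 2 h. They stay in the counts, and in those of lists they were LEA4-5, CER1, JAZ1 and LHCB4.1 in WT at 5 h against 0 h, P5CR, CER1 and LHCB4.1 against 2 h, LHCA4 and ANAC029 in ahp4 at 2 h against 0 h and ANAC029 at 5 h. Between genotypes they were ANAC029 at 0 h and LEA4-5 and LHCB4.1 at 5 h, and in the genotype differences P5CR, LHCA4 and ANAC029 at 2 h and LEA4-5 and CER1 at 5 h.

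**Figure D1:**
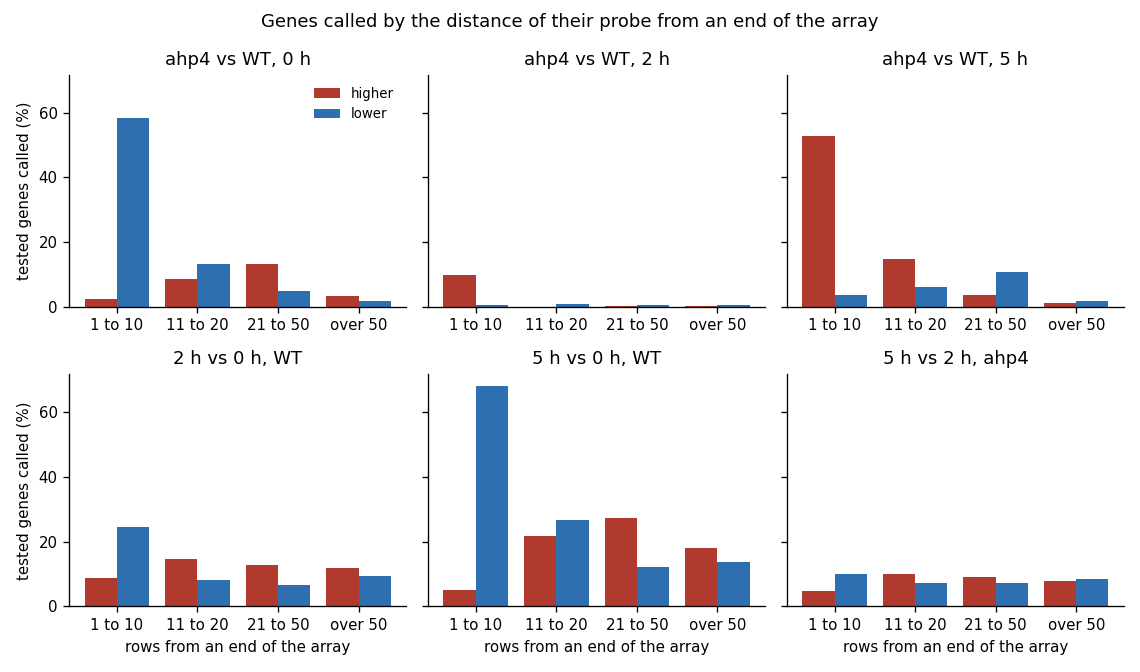
Percent of tested genes called higher or lower (bars) by the distance of their probe from an end of the array in rows, for 6 comparisons. In the outermost 10 rows 68.3% of genes were called lower in WT at 5 h against 0 h, and 10.1% in ahp4 at 5 h against 2 h.

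AHP4 transcript signal was lower in ahp4 than in WT at every time. Its probe matches chromosome 3, positions 5555308 to 5555367 of the TAIR10 assembly, and lay 5 rows from an end of the array. It was not well above background on any ahp4 array. On the log2 scale relative to each array's 75th percentile, WT averaged -1.89 ± 0.49 (SD, n = 3) at 0 h, -3.33 ± 2.08 at 2 h and -4.49 ± 0.64 at 5 h, where 2 of 3 arrays were well above background. The corresponding ahp4 means were -6.50 ± 0.40, -8.09 ± 0.05 and -8.36 ± 0.08. The signal was lower in ahp4 at least 24.4-fold, 7.38-fold and 4.49-fold at 0, 2 and 5 h (limma adjusted p = 0.00063, 0.00411 and 0.00242). All 3 ahp4 arrays lay below all 3 WT arrays at each time, for an exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow. Other genes within 10 rows of an end had a median log2 difference of -1.99 at 0 h, 0.16 at 2 h and 1.94 at 5 h. With normexp background correction the differences at 2 and 5 h were -1.49 and -0.78 and were no longer called (adjusted p = 0.0612 and 0.17).

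**Figure D2:**
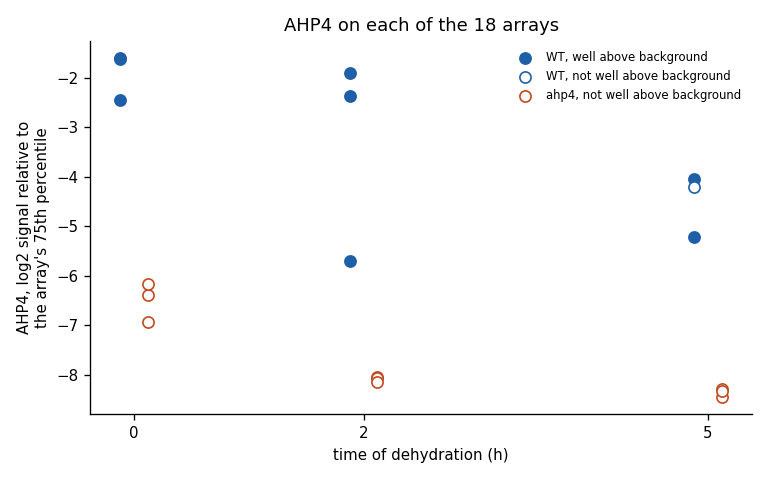
AHP4 signal on each array (points), as log2 relative to the array's 75th percentile, against the time of dehydration in h; filled points were well above background. On none of the 9 ahp4 arrays was the probe well above background, and WT means go from -1.89 at 0 h to -4.49 at 5 h.

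The first 3 comparisons ask how detached WT leaves changed while drying. No undetached plants were sampled at 2 and 5 h, so drying, detachment and hour cannot be told apart. At 2 h lists of abscisic acid metabolism and phosphatases, protective proteins, jasmonate, heat shock and flavonoids were called upward against 0 h, and those of abscisic acid receptors and type-A response regulators downward. With estimated correlation only the jasmonate and phosphatase calls held. Of 20369 genes tested, 2418 rose and 1911 fell. Jasmonate genes gave 23 rises and 0 falls among 24 measured (camera adjusted p = 3.42e-18, or 0.00833 estimated). They took in the synthesis enzymes AOC3 (AT3G25780, 6.95 ± 0.30), LOX3 (AT1G17420, 5.97 ± 0.28) and OPR3 (AT2G06050, 4.24 ± 0.16) and the repressor gene JAZ7 (AT2G34600, 6.60 ± 0.33). The largest rises included CYP94B1 (AT5G63450, 10.42 ± 0.47) and CYP94B3 (AT3G48520, 9.91 ± 0.82), which oxidise the hormone, and the methyltransferase gene BSMT1 (AT3G11480, at least 1001-fold). In abscisic acid metabolism there were 5 rises and 0 falls among 11 measured (adjusted p = 0.00779, or 0.0617 estimated). NCED3 (AT3G14440, 4.27 ± 0.22), of the rate-limiting synthesis step, and CYP707A1 (AT4G19230, 2.78 ± 0.28), of hydroxylation, both rose. The clade A phosphatases, which act as negative regulators of abscisic acid signalling, gave 8 rises and 0 falls among 9 measured (adjusted p = 5.28e-08, or 0.00833 estimated). HAI2 (AT1G07430, 4.81 ± 0.33), ABI2 (AT5G57050, 3.98 ± 0.18) and HAB1 (AT1G72770, 3.29 ± 0.17) rose. Their receptor partners moved the other way, with 1 rise and 6 falls among 9 measured (adjusted p = 0.00755, or 0.216 estimated). The receptor genes PYL5 (AT5G05440, -2.62 ± 0.31), PYL4 (AT2G38310, -2.60 ± 0.31) and PYL6 (AT2G40330, at least 21.3-fold) fell most.

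Protective proteins gave 17 rises and 0 falls among 18 measured (adjusted p = 9.42e-11, or 0.0617 estimated). COR15A (AT2G42540, 5.45 ± 0.33), RD29A (AT5G52310, 4.94 ± 0.32) and ERD10 (AT1G20450, 3.01 ± 0.20) rose. For the transcription factors of dehydration there were 15 rises and 0 falls among 21 measured (adjusted p = 1.46e-10, or 0.0763 estimated), led by the NAC genes ANAC019 (AT1G52890, 6.24 ± 0.27) and RD26 (AT4G27410, 5.23 ± 0.26), with MYB44 (AT5G67300, 4.01 ± 0.22) and the homeobox gene ATHB12 (AT3G61890, 3.56 ± 0.19). Chaperone genes followed, with 9 rises and 0 falls among 15 measured (adjusted p = 0.000138, or 0.259 estimated). Here HSFA2 (AT2G26150, 8.24 ± 0.41), a heat shock factor, HSP17.8 (AT1G07400, 6.96 ± 0.45) and HSP70 (AT3G12580, 5.74 ± 0.45) were highest. The flavonoid list gave 13 rises and 1 fall among 19 measured, 14 and 1 adjusted over the list alone (adjusted p = 3.93e-05, or 0.259 estimated). The anthocyanin regulator PAP1 (AT1G56650, 6.57 ± 0.61) rose and MYBL2 (AT1G71030, -2.71 ± 0.22), a repressor of the pathway, fell. Cuticle genes gave 12 rises and 1 fall among 30 measured (adjusted p = 0.000205, or 0.327 estimated). The wax synthase gene WSD1 (AT5G37300, 4.47 ± 0.36) and the elongase KCS2 (AT1G04220, 4.38 ± 0.26) rose. Aquaporin genes gave 7 rises and 1 fall among 16 measured (adjusted p = 0.00526, or 0.416 estimated), of which PIP2;3 (AT2G37180, 5.56 ± 0.29) and PIP1;4 (AT4G00430, 3.02 ± 0.19) rose most. Genes against reactive oxygen gave 5 rises and 0 falls among 18 measured (adjusted p = 0.0293, or 0.327 estimated, 0.119 with normexp background and 0.0721 with quantile normalization). GSTU4 (AT2G29460, 4.28 ± 0.54) and AOX1A (AT3G22370, 2.20 ± 0.22) rose. Proline and sugar osmolyte genes showed 4 rises and 2 falls among 9 measured (adjusted p = 0.246), of which P5CS1 (AT2G39800, 3.96 ± 0.38), of proline synthesis, rose by the larger amount than PRODH2 (AT5G38710, 2.03 ± 0.35), of its breakdown.

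Type-A response regulators, which respond first to cytokinin, gave 0 rises and 5 falls among 9 measured (adjusted p = 0.00479, or 0.327 estimated). ARR16 (AT2G40670, -2.69 ± 0.34), ARR9 (AT3G57040, -1.93 ± 0.42) and ARR4 (AT1G10470, -1.90 ± 0.38) fell, and so did the receptor gene AHK2 (AT5G35750, -1.50 ± 0.16). Cytokinin metabolism gave 3 rises and 3 falls among 13 measured (adjusted p = 0.941). CKX1 (AT2G41510, -2.61 ± 0.23), of degradation, and IPT3 (AT3G63110, -2.04 ± 0.48), of synthesis, fell, while CKX5 (AT1G75450, 2.07 ± 0.48) rose. Growth genes of the cell wall gave 2 rises and 5 falls among 11 measured (adjusted p = 0.211). The expansin EXPA8 (AT2G40610, -7.73 ± 0.55, second probe -8.18) fell furthest of the named genes, EXPA1 (AT1G69530, -2.73 ± 0.30) fell and EXPA10 (AT1G26770, 3.72 ± 0.44) rose. Other large rises were RAP2.6 (AT1G43160, 9.45 ± 0.48, n = 2 in WT at 2 h), DIP2 (AT5G03210, 9.30 ± 0.24) and CSLA01 (AT4G16590, at least 187-fold). By 1 of 2 probes they held HSFA6B (AT3G22830, at least 185-fold, second probe 0.48) and UGT76E12 (AT3G46660, 9.16 ± 0.86, detected on 1 of 3 arrays of WT at 0 h, second probe -0.12). Of the 8 largest falls, 5 lay within 2 rows of an array end. They were FEI1 (AT1G31420, -7.30 ± 0.79, detected on 1 of 3 arrays of WT at 2 h) and Cand6 (AT5G02630, -7.02 ± 0.53, detected on 1 of 3 arrays of WT at 2 h), then PAB8 (AT1G49760, 1 array of WT at 2 h, second probe -0.30), HO3 (AT1G69720, -5.98 ± 0.70, detected on 1 of 3 arrays of WT at 2 h) and FADA (AT4G27030, -5.31 ± 0.57, detected on 1 of 3 arrays of WT at 2 h). Another was AL3 (AT3G42790, -6.26 ± 1.26, detected on 2 of 3 arrays of WT at 2 h). Among called loci with a second probe, it moved at least 2-fold the same way for 86.4% of the genes that rose and 83.8% of those that fell.

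At 5 h in WT lists of abscisic acid metabolism and phosphatases, protective proteins, cuticle and senescence were called upward against 0 h, and photosynthesis downward. With estimated correlation only the phosphatase call held, and that of photosynthesis was also lost with the spike-in slope. Against 0 h, 3823 of 20229 genes rose and 3095 fell. All measured clade A phosphatase genes had risen, with 8 rises and 0 falls among 8 measured (adjusted p = 2.43e-06, or 0.0434 estimated). The seed phosphatase gene AHG1 (AT5G51760, at least 169-fold, n = 2 in WT at 5 h) stood beside ABI2 (4.54 ± 0.18) and HAB1 (3.77 ± 0.17). Abscisic acid metabolism gave 9 rises and 0 falls among 12 measured (adjusted p = 0.00547, or 0.0946 estimated). NCED3 (5.38 ± 0.22), CYP707A1 (4.59 ± 0.28) and the cofactor gene ABA3 (AT1G16540, 2.00 ± 0.25) rose. Protective proteins gave 15 rises and 0 falls among 16 measured (adjusted p = 1.39e-07, or 0.137 estimated). LEA7 (AT1G52690, 11.73 ± 0.54), COR15A (6.43 ± 0.33) and RD22 (AT5G25610, 3.83 ± 0.17) rose. Dehydration factors gave 16 rises and 0 falls among 20 measured (adjusted p = 7.55e-07, or 0.202 estimated). ANAC019 (6.15 ± 0.27), RD26 (5.56 ± 0.26) and the bZIP gene ABF2 (AT1G45249, 3.27 ± 0.20) rose. Osmolyte genes showed 3 rises and 2 falls among 8 measured (adjusted p = 0.158). P5CS1 (5.45 ± 0.38) and P5CS2 (AT3G55610, 2.92 ± 0.19, n = 2 in WT at 5 h), of proline synthesis, rose and PRODH1 (AT3G30775, -2.26 ± 0.33), of its breakdown, fell. Cuticle genes gave 20 rises and 1 fall among 29 measured, 20 and 2 adjusted over the list alone (adjusted p = 0.000187, or 0.316 estimated). The elongase gene KCS2 (6.99 ± 0.26), WSD1 (6.10 ± 0.36) and CER3 (AT5G57800, 3.21 ± 0.24), of alkane synthesis, rose. Senescence genes gave 7 rises and 1 fall among 13 measured (adjusted p = 0.0047, or 0.202 estimated). The sugar exporter SWEET15 (AT5G13170, 9.62 ± 0.51) and the chlorophyll breakdown genes NYE2 (AT4G11910, 3.44 ± 0.36) and PAO (AT3G44880, 3.16 ± 0.21, n = 2 in WT at 5 h) rose.

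Jasmonate genes gave 18 rises and 0 falls among 22 measured, 19 and 0 adjusted over the list alone (adjusted p = 1.08e-06, or 0.137 estimated). CYP94B3 (9.92 ± 0.82), JAZ7 (6.13 ± 0.33) and LOX3 (4.37 ± 0.28) rose. Flavonoid genes gave 15 rises and 1 fall among 19 measured (adjusted p = 0.000293, or 0.316 estimated). PAP1 (4.97 ± 0.61), TT8 (AT4G09820, 4.43 ± 0.48) and TT7 (AT5G07990, 3.37 ± 0.42), of flavonoid hydroxylation, rose. Chaperones gave 10 rises and 1 fall among 15 measured (adjusted p = 0.000312, or 0.316 estimated), and HSP21 (AT4G27670, at least 187-fold, n = 2 in WT at 5 h) of the plastid, HSP17.8 (6.60 ± 0.45) and HSP17.6II (AT5G12020, 5.12 ± 0.39) rose. Reactive oxygen genes gave 7 rises and 0 falls among 17 measured (adjusted p = 0.0487, or 0.316 estimated, 0.223 with normexp background, 0.0799 with quantile normalization, 0.0558 with the position trend removed, 0.0535 with the outermost 50 rows left out and 0.053 with a replicate block). The peroxidase gene APX2 (AT3G09640, at least 53.4-fold), AOX1A (3.09 ± 0.22) and GPX6 (AT4G11600, 1.43 ± 0.13) rose. Photosynthesis genes gave 0 rises and 7 falls among 23 measured (adjusted p = 0.00202, or 0.566 estimated, and 0.234 divided by the spike-in slope). RBCS1B (AT5G38430, -4.26 ± 0.41), of the Rubisco small subunit, fell, and LHCB3 (AT5G54270, -1.38 ± 0.30, second probe -0.67) of the antenna fell by 1 probe. Also called lower were PSBO1 (AT5G66570, -1.38 ± 0.20, second probe -0.61, probe 11 rows from an array end) and LHCB4.1 (AT5G01530, 1 array of WT at 5 h, second probe -0.10, probe 5 rows from an array end). Growth genes gave 2 rises and 6 falls among 11 measured (adjusted p = 0.0541), with EXPA8 (-9.60 ± 0.55, detected on 2 of 3 arrays of WT at 5 h) and XTH4 (AT2G06850, -2.68 ± 0.24) lower and XTH22 (AT5G57560, 2.81 ± 0.36) higher. Of cytokinin genes CKX1 (-3.05 ± 0.23), IPT3 (-2.77 ± 0.48) and ARR4 (-1.47 ± 0.38) fell and the type-A list gave 0 rises and 2 falls among 9 measured (adjusted p = 0.286). Further large rises were BSMT1 (at least 1508-fold), MAPKKK18 (AT1G05100, 9.68 ± 0.50) and TSPO (AT2G47770, 10.55 ± 0.40, second probe 10.84), of a membrane protein induced by abscisic acid. HSFA6B (at least 551-fold) and UGT76E12 (10.66 ± 0.86, detected on 1 of 3 arrays of WT at 0 h, second probe -0.56) rose too. Of the 8 largest falls, 5 had a probe within 7 rows of an array end. They were BZIP53 (AT3G62420, 1 array of WT at 5 h, second probe 1.41), NIK3 (AT1G60800, at least 292-fold), PnsL3 (AT3G01440, at least 262-fold), SAR2 (AT4G02080, at least 239.9-fold) and CRR7 (AT5G39210, at least 234-fold). The others were EXPA8, ASPG1 (AT3G18490, 1 array of WT at 5 h, second probe -0.26) and ARD1 (AT4G14716, -7.87 ± 0.23, n = 2 in WT at 5 h). Second probes, where present, moved at least 2-fold the same way for 65.1% of rises and 67.9% of falls.

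Between 2 and 5 h in WT, jasmonate, salicylate and photosynthesis lists were called downward and senescence and cuticle lists upward. No list call held with estimated correlation. 2233 genes rose and 1919 fell of 20216. The jasmonate list gave 0 rises and 14 falls among 22 measured, 0 and 15 adjusted over the list alone (adjusted p = 3.1e-08, or 0.235 estimated). AOC3 (-2.68 ± 0.30), OPR3 (-2.33 ± 0.16) and AOS (AT5G42650, -2.14 ± 0.23) fell. Salicylate and defence genes gave 0 rises and 4 falls among 17 measured (adjusted p = 0.0098, or 0.703 estimated, and 0.0701 by fry). ICS1 (AT1G74710, -1.80 ± 0.54), of salicylate synthesis, and EDS1 (AT3G48090, -1.59 ± 0.36) fell. Photosynthesis genes gave 0 rises and 8 falls among 23 measured (adjusted p = 7.65e-05, or 0.667 estimated, and 0.0507 divided by the spike-in slope). RBCS1B (-2.20 ± 0.41) fell. Senescence genes gave 6 rises and 0 falls among 13 measured (adjusted p = 0.00639, or 0.429 estimated, and 0.0819 in the deposited table). SWEET15 (5.92 ± 0.51), NYE2 (2.63 ± 0.36) and NYC1 (AT4G13250, 2.59 ± 0.23), of chlorophyll b breakdown, rose. The cuticle list gave 9 rises and 1 fall among 29 measured, 10 and 1 adjusted over the list alone (adjusted p = 0.0427, or 0.703 estimated, 0.279 with normexp background, 0.0985 with quantile normalization, 0.0688 in the deposited table and 0.0801 with the position trend removed). KCS2 (2.61 ± 0.26) and CER3 (2.12 ± 0.24) rose. Of type-A response regulators ARR16 (2.27 ± 0.34) and ARR9 (1.79 ± 0.42) rose, within 5 rises and 0 falls among 9 measured (adjusted p = 0.163), of which ARR17 (AT3G56380) was below background in both groups. Largest rises were HSP21 (at least 161-fold, n = 2 in WT at 5 h), PAP20 (AT3G52780, at least 79.5-fold), MAN1 (AT1G02310, 6.05 ± 0.53), and AHG1 (5.89 ± 0.49, n = 2 in WT at 5 h). SCPL19 (AT5G09640, 5.79 ± 0.60, detected on 1 of 3 arrays of WT at 2 h), HIPP22 (AT1G22990, 5.56 ± 0.55, probe 9 rows from an array end) and APX2 (5.28 ± 0.50, detected on 1 of 3 arrays of WT at 2 h) came next. Of the 8 largest falls, 5 lay within 50 rows of an end, and only 2 of 5 second probes fell 2-fold. Those were of SUS2 (AT1G80070, 1 array of WT at 5 h, second probe -3.12, probe 14 rows from an array end) and IAA18 (AT1G51950, 1 array of WT at 5 h, second probe -1.69), of which the second probe of SUS2 was not called (adjusted p = 0.17). Of the others, SVB (AT1G56580, 1 array of WT at 5 h, second probe 0.29), BZIP53 (1 array of WT at 5 h, second probe 1.17, probe 7 rows from an array end) and ASPG1 (1 array of WT at 5 h, second probe -0.43) had a second probe that did not fall 2-fold. RPL34 (AT1G69620, -7.19 ± 0.99, n = 2 in WT at 5 h, detected on 2 of 3 arrays of WT at 5 h, probe 8 rows from an array end), MKK4 (AT1G51660, at least 97.8-fold, n = 2 in WT at 2 h) and ARD1 (-8.12 ± 0.23, n = 2 in WT at 5 h) had none.

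The next 3 comparisons ask the same of ahp4. At 2 h lists of jasmonate, abscisic acid metabolism and phosphatases, protective proteins and chaperones were called upward. With estimated correlation all of these but chaperones held, and no other list. Of 20299 genes, 2810 rose and 3626 fell. The share of rises among called genes, 43.7%, was 55.7% when arrays were scaled to the median of bright probes, which moved the median of all genes from -0.22 to 0.01. Jasmonate genes gave 22 rises and 1 fall among 23 measured (adjusted p = 2.16e-16, or 0.0174 estimated). AOC3 (6.89 ± 0.30), LOX3 (6.09 ± 0.28), OPR3 (4.20 ± 0.16) and JAZ7 (7.27 ± 0.33) rose. Clade A phosphatases gave 8 rises and 0 falls among 9 measured (adjusted p = 1.05e-06, or 0.0174 estimated). HAI2 (5.12 ± 0.33), ABI2 (4.43 ± 0.18) and HAB1 (3.65 ± 0.17) rose. Abscisic acid metabolism gave 9 rises and 0 falls among 12 measured, 10 and 0 adjusted over the list alone (adjusted p = 0.00127, or 0.0254 estimated). NCED3 (4.39 ± 0.22) and CYP707A1 (1.74 ± 0.28, second probe 0.99) rose. Receptor genes gave 1 rise and 5 falls among 9 measured (adjusted p = 0.125). PYL5 (-2.70 ± 0.31), PYL2 (AT2G26040, -1.73 ± 0.20) and PYL6 (at least 13.8-fold) fell. Protective proteins gave 17 rises and 0 falls among 18 measured (adjusted p = 2.67e-11, or 0.0499 estimated). COR15A (5.62 ± 0.33), RD29A (4.69 ± 0.32) and LEA7 (10.65 ± 0.54, detected on 2 of 3 arrays of ahp4 at 0 h) rose. Dehydration factors gave 17 rises and 0 falls among 21 measured (adjusted p = 9.47e-10, or 0.0949 estimated). ANAC019 (6.01 ± 0.27), RD26 (5.46 ± 0.26) and MYB44 (3.82 ± 0.22) rose.

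Chaperones gave 10 rises and 1 fall among 15 measured (adjusted p = 1.4e-05, or 0.207 estimated). HSFA2 (6.62 ± 0.41) and HSP70 (4.62 ± 0.45) rose. Aquaporins gave 7 rises and 0 falls among 16 measured, 8 and 0 adjusted over the list alone (adjusted p = 0.000457, or 0.357 estimated). PIP2;3 (5.52 ± 0.29), PIP1;4 (3.06 ± 0.19) and the tonoplast gene TIP1;1 (AT2G36830, 2.17 ± 0.28) rose. Flavonoid genes gave 11 rises and 1 fall among 19 measured (adjusted p = 0.00506, or 0.408 estimated), with PAP1 (6.81 ± 0.61) higher and MYBL2 (-3.58 ± 0.22) lower. Cuticle genes gave 10 rises and 2 falls among 30 measured (adjusted p = 0.00941, or 0.443 estimated). WSD1 (4.42 ± 0.36), KCS2 (3.62 ± 0.26) and CER2 (AT4G24510, 1.48 ± 0.21) rose. Reactive oxygen genes gave 4 rises and 1 fall among 17 measured (adjusted p = 0.00941, or 0.308 estimated). GSTU4 (4.28 ± 0.54) and the ascorbate recycling gene DHAR1 (AT1G19570, 2.80 ± 0.46) rose. Photosynthesis genes gave 5 rises and 0 falls among 23 measured (adjusted p = 0.000896, or 0.45 estimated, and 0.0894 divided by the spike-in slope). Called among them were PSBO1 (1.76 ± 0.22, n = 2 in ahp4 at 0 h, second probe 0.43, probe 11 rows from an array end), LHCB2.2 (AT2G05070, 1.18 ± 0.36, second probe 0.77) and LHCA4 (AT3G47470, 1 array of ahp4 at 0 h, second probe 0.25). Type-A response regulators gave 0 rises and 5 falls among 9 measured (adjusted p = 0.163). ARR16 (-2.45 ± 0.34), ARR9 (-1.99 ± 0.42) and ARR4 (-1.49 ± 0.38) fell. The receptor gene AHK2 (-2.34 ± 0.16) and ARR1 (AT3G16857, -1.38 ± 0.12), a type-B regulator, fell with them. Guard cell genes gave 0 rises and 5 falls among 14 measured (adjusted p = 0.0725). The lineage gene FAMA (AT3G24140, -1.61 ± 0.16) and EPF1 (AT2G20875, -1.52 ± 0.28) fell. The largest rises were LEA7, BSMT1 (at least 1227-fold), CYP94B1 (10.26 ± 0.47) and the redox factor gene RRTF1 (AT4G34410, at least 483-fold). With them rose the terpene genes TPS03 (AT4G16740, at least 379-fold, second probe 8.43) and CYP82G1 (AT3G25180, 9.67 ± 0.87, detected on 2 of 3 arrays of ahp4 at 0 h), ANNAT4 (AT2G38750, at least 681-fold, probe 11 rows from an array end) and UGT76E12 (at least 899.6-fold). The largest falls were PYL6, EXPA8 (-6.53 ± 0.55, second probe -6.86), CYP71B36 (AT3G26320, at least 35.6-fold) and HBI1 (AT2G18300, -5.47 ± 0.72), of a growth-promoting factor. The defensin genes PDF1.3 (AT2G26010, -5.24 ± 1.49) and PDF1.2c (AT5G44430, -4.86 ± 1.72, n = 2 in ahp4 at 0 h), BBX14 (AT1G68520, -5.15 ± 0.29, second probe -2.41) and MYB48 (AT3G46130, -4.95 ± 0.33, detected on 2 of 3 arrays of ahp4 at 2 h) followed. Second probes, where present, moved at least 2-fold the same way for 72.8% of rises and 56.8% of falls.

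By 5 h all protective and phosphatase genes measured in ahp4 were called higher. Chaperone, flavonoid and senescence lists were called upward and photosynthesis downward. With estimated correlation only the calls of phosphatases and abscisic acid metabolism held, and that of photosynthesis was also lost with normexp background and in the deposited table. 3193 genes rose and 3962 fell of 20299. Rises made up 44.6% of calls, and 55.5% with the median of bright probes as the scale. Protective proteins gave 18 rises and 0 falls among 18 measured (adjusted p = 6.34e-12, or 0.052 estimated). LEA7 (13.07 ± 0.54, detected on 2 of 3 arrays of ahp4 at 0 h), COR15A (7.05 ± 0.33) and RAB18 (AT5G66400, 5.81 ± 0.35, second probe 7.61) rose. Phosphatases gave 9 rises and 0 falls among 9 measured (adjusted p = 1.4e-08, or 0.0106 estimated). HAI2 (5.91 ± 0.33), ABI2 (4.97 ± 0.18) and HAB1 (4.03 ± 0.17) rose. Abscisic acid metabolism gave 11 rises and 1 fall among 12 measured (adjusted p = 0.000158, or 0.0143 estimated). NCED3 (5.51 ± 0.22) and CYP707A1 (3.31 ± 0.28) rose and ABA2 (AT1G52340, -1.21 ± 0.14), of a late step of synthesis, fell. The receptor genes PYL4 (-3.58 ± 0.31), PYL2 (-2.35 ± 0.20) and PYL6 (at least 18.9-fold) fell within 0 rises and 5 falls among 9 measured (adjusted p = 0.0339, or 0.265 estimated). Jasmonate genes gave 20 rises and 1 fall among 23 measured (adjusted p = 1.84e-08, or 0.0642 estimated). CYP94B3 (9.02 ± 0.82), JAZ7 (5.74 ± 0.33), LOX3 (4.19 ± 0.28) and JAZ1 (AT1G19180, 4.19 ± 0.28) rose. Dehydration factors gave 17 rises and 1 fall among 21 measured (adjusted p = 6.68e-08, or 0.139 estimated). CBF4 (AT5G51990, at least 170.0-fold), ANAC019 (5.49 ± 0.27) and RD26 (5.40 ± 0.26) rose. Chaperones gave 13 rises and 1 fall among 15 measured (adjusted p = 4.42e-07, or 0.139 estimated). HSP17.4 (AT3G46230, at least 185-fold) and HSP70 (5.84 ± 0.45) rose.

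Flavonoid genes gave 16 rises and 1 fall among 19 measured (adjusted p = 3.92e-06, or 0.166 estimated), with PAP1 (6.52 ± 0.61), UGT79B1 (AT5G54060, 5.86 ± 0.67) and TT7 (3.74 ± 0.42) higher and MYBL2 (-3.21 ± 0.22) lower. Cuticle genes gave 15 rises and 3 falls among 30 measured (adjusted p = 0.000116, or 0.293 estimated). KCS2 (5.81 ± 0.26), WSD1 (5.28 ± 0.36) and CER3 (2.35 ± 0.24) rose. Senescence genes gave 9 rises and 2 falls among 15 measured, 10 and 2 adjusted over the list alone (adjusted p = 0.00247, or 0.142 estimated). SWEET15 (10.00 ± 0.51), PAO (2.34 ± 0.19) and PPH (AT5G13800, 1.95 ± 0.18), of chlorophyll breakdown, rose. Reactive oxygen genes gave 6 rises and 1 fall among 17 measured (adjusted p = 0.00137, or 0.155 estimated). APX2 (at least 36.9-fold), GSTU4 (4.25 ± 0.54) and AOX1A (2.72 ± 0.22) rose. Photosynthesis genes gave 1 rise and 10 falls among 23 measured (adjusted p = 0.0216, or 0.657 estimated, 0.0556 with normexp background and 0.124 in the deposited table). RBCS1B (-4.12 ± 0.41), LHCB2.3 (AT3G27690, -3.61 ± 0.50) and LHCB3 (-2.27 ± 0.30) fell. The proline genes P5CS1 (5.79 ± 0.38) and P5CS2 (2.38 ± 0.19, n = 2 in ahp4 at 0 h) rose within 5 rises and 3 falls among 9 measured (adjusted p = 0.318). No cytokinin list was called. ARR15 (AT1G74890, -2.57 ± 0.89), ARR5 (AT3G48100, -1.99 ± 0.47), AHK2 (-2.22 ± 0.16) and the response factor gene CRF5 (AT2G46310, -1.35 ± 0.22, probe 11 rows from an array end) fell. CKX1 (-4.15 ± 0.23) and CKX4 (AT4G29740, -2.27 ± 0.41) fell too, and metabolism gave 1 rise and 4 falls among 13 measured (adjusted p = 0.749). Largest rises also took in BSMT1 (at least 1637-fold), TSPO (11.23 ± 0.40, second probe 11.01) and LEA18 (AT2G35300, at least 424-fold). They held HSFA6B (at least 403-fold, second probe 2.30), UGT76E12 (at least 1191-fold, second probe 0.55) and PREP1 (AT3G19170, 9.68 ± 0.56, n = 2 in ahp4 at 0 h, detected on 1 of 3 arrays of ahp4 at 0 h, second probe 2.09) as well. Largest falls were EXPA8 (-8.55 ± 0.55, detected on 2 of 3 arrays of ahp4 at 5 h, second probe -9.53), CYP71B36 (at least 48.7-fold), HBI1 (-6.80 ± 0.72) and the nitrate transporter gene NRT2.5 (AT1G12940, at least 16.9-fold). The defensin genes PDF1.3 (-6.72 ± 1.49) and PDF1.2c (-6.46 ± 1.72, n = 2 in ahp4 at 0 h) fell, with AACT1 (AT5G61160, -8.60 ± 0.80, detected on 2 of 3 arrays of ahp4 at 5 h) and PKS4 (AT5G04190, -6.84 ± 0.47, detected on 2 of 3 arrays of ahp4 at 5 h). Second probes, where present, moved at least 2-fold the same way for 76.3% of rises and 66% of falls.

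**Figure D3:**
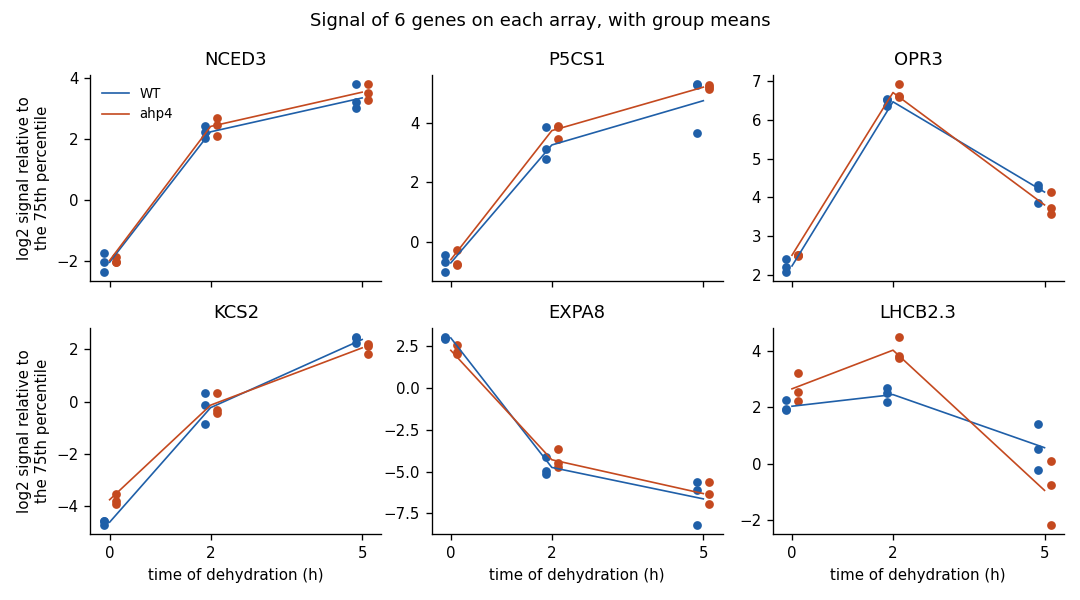
Signal of 6 genes chosen after their values were seen, as log2 relative to the array's 75th percentile, on each array (points) with group means (lines), against the time of dehydration in h. NCED3 rose by 5.38 in WT and by 5.51 in ahp4 at 5 h, and EXPA8 lay -9.60 and -8.55 from its level at 0 h.

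Between 2 and 5 h in ahp4, photosynthesis, jasmonate, salicylate and growth lists were called downward, and protective and flavonoid lists upward. No list call held with estimated correlation. 1607 genes rose and 1669 fell of 20383. Photosynthesis genes gave 0 rises and 21 falls among 26 measured (adjusted p = 4.08e-12, or 0.329 estimated). LHCB2.3 (-4.98 ± 0.50, second probe -5.03), LHCB3 (-3.08 ± 0.30), RBCS1B (-3.18 ± 0.41) and PSBO2 (AT3G50820, -1.54 ± 0.19) fell. Jasmonate genes gave 0 rises and 16 falls among 24 measured, 0 and 17 adjusted over the list alone (adjusted p = 1.56e-09, or 0.167 estimated). AOC3 (-3.88 ± 0.30), OPR3 (-2.90 ± 0.16), JAZ6 (AT1G72450, -2.33 ± 0.13) and AOS (-2.23 ± 0.23) fell. Salicylate genes gave 0 rises and 6 falls among 17 measured (adjusted p = 0.00578, or 0.607 estimated). PAD4 (AT3G52430, -2.91 ± 0.53), ICS1 (-2.73 ± 0.54) and EDS1 (-2.57 ± 0.36) fell. Cell wall growth genes gave 0 rises and 4 falls among 11 measured, 0 and 6 adjusted over the list alone (adjusted p = 0.0187, or 0.363 estimated). XTH4 (-2.57 ± 0.24), EXPA10 (-1.55 ± 0.44) and EXPA5 (AT3G29030, -1.34 ± 0.26) fell. Aquaporins gave 0 rises and 4 falls among 16 measured (adjusted p = 0.00566, or 0.461 estimated). PIP2;3 (-2.89 ± 0.29) and PIP2;2 (AT2G37170, -2.40 ± 0.45) fell. On the rising side, flavonoid genes gave 10 rises and 0 falls among 19 measured (adjusted p = 0.00062, or 0.392 estimated). TT7 (3.61 ± 0.42), TT8 (2.02 ± 0.48) and FLS1 (AT5G08640, 1.78 ± 0.41) rose. Protective proteins gave 8 rises and 0 falls among 18 measured (adjusted p = 0.00154, or 0.392 estimated). LEA4-5 (AT5G06760, 3.48 ± 0.49), RAB18 (2.10 ± 0.35) and RD22 (1.34 ± 0.17) rose. The phosphatases gave 2 rises and 0 falls among 9 measured (adjusted p = 0.00533, or 0.3 estimated), which were AHG1 (5.09 ± 0.44) and HAI3 (AT2G29380, at least 46.8-fold, probe 2 rows from an array end). Senescence genes gave 6 rises and 1 fall among 15 measured, 7 and 2 adjusted over the list alone (adjusted p = 0.0119, or 0.329 estimated). SWEET15 (5.95 ± 0.51), NYE2 (3.35 ± 0.36) and NYC1 (2.41 ± 0.23) rose. The cuticle list gave 4 rises and 0 falls among 30 measured (adjusted p = 0.0293, or 0.607 estimated). KCS2 (2.19 ± 0.26) and CER3 (1.48 ± 0.24) rose. CKX4 (-4.31 ± 0.41) and CKX5 (-1.68 ± 0.48) of cytokinin degradation fell, as did CBF2 (AT4G25470, -3.21 ± 0.44). The largest rises also held HSP21 (6.70 ± 0.81, detected on 1 of 3 arrays of ahp4 at 2 h), PAP20 (at least 51.5-fold), SCPL19 (at least 59.4-fold) and MAN1 (6.55 ± 0.53, second probe 7.11). The transporter genes OCT1 (AT1G73220, at least 25.7-fold) and ZIP9 (AT4G33020, 5.63 ± 1.65, detected on 1 of 3 arrays of ahp4 at 2 h) rose with them. The largest falls held CYP82G1 (-6.77 ± 0.87), PP2-A5 (AT1G65390, -6.55 ± 0.81), MYB24 (AT5G40350, -5.95 ± 0.44, detected on 1 of 3 arrays of ahp4 at 5 h) and NAC025 (AT1G61110, at least 27-fold, second probe -3.89, probe 8 rows from an array end). The methionine sulfoxide reductase genes MSRB6 (AT4G04840, -4.83 ± 0.62) and MSRB9 (AT4G21850, -4.66 ± 0.57, second probe -4.70) and the kinase gene CRK23 (AT4G23310, -4.48 ± 0.80, detected on 1 of 3 arrays of ahp4 at 5 h) fell too. Second probes, where present, moved at least 2-fold the same way for 85.9% of rises and 88.4% of falls.

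**Figure D4:**
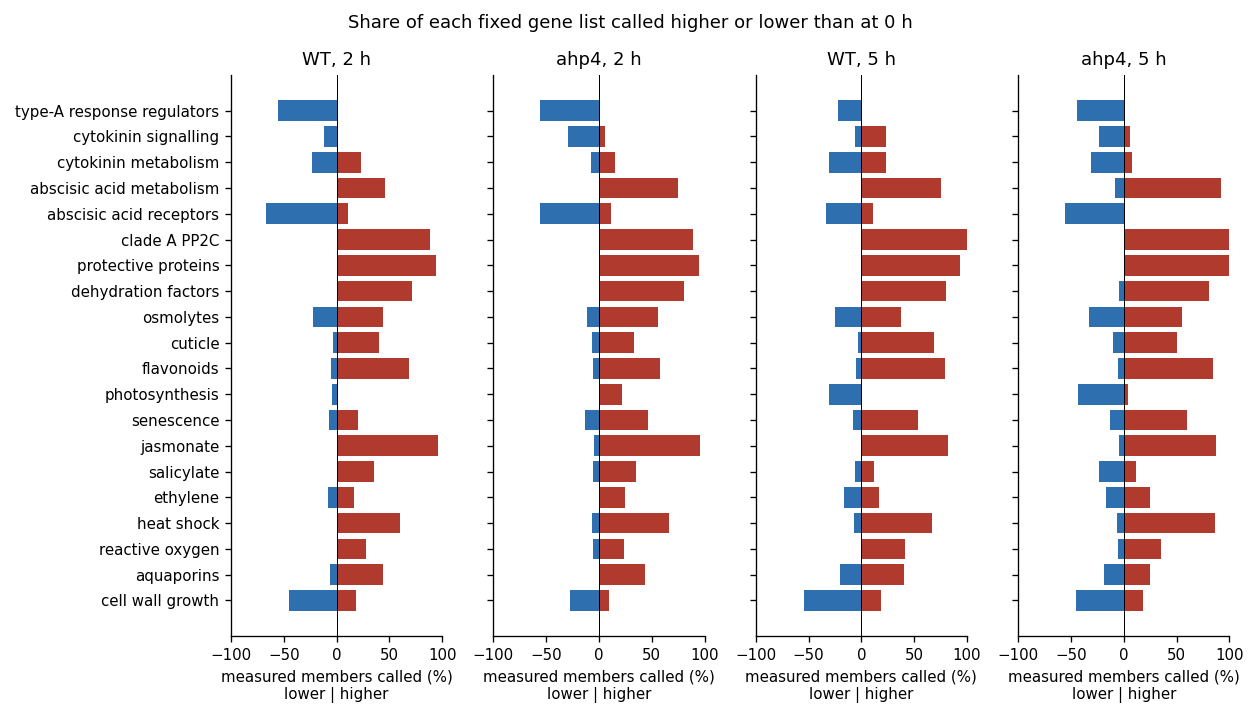
Percent of the measured members of 20 fixed gene lists called higher (right) or lower (left) than at 0 h, for each genotype and time. Jasmonate genes were higher in 23 of 24 cases in WT at 2 h and 22 of 23 in ahp4.

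The dehydration responses of the 2 genotypes overlapped. At 2 h, 1738 genes rose in both against 333 for independent lists, and 1467 fell in both against 341. 126 genes were called in opposite directions. At 5 h the counts were 2082 against 595, 1861 against 599 and 397. Across genes, which are not independent replicates, the fold changes of the genotypes correlated with Pearson's r = 0.666 at 2 h and 0.574 at 5 h, and no array enters both.

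The comparison of ahp4 with WT at 0 h asks what the mutation changed in leaves before drying. Single genes were higher in ahp4, and no list was called upward. 932 of 20299 genes were higher in ahp4 and 813 lower, but 2 probes of the same locus were called the same way for only 49 and 16 loci. The following genes were chosen from these after their values were seen. CYP81F4 (AT4G37410, 2.73 ± 0.45, second probe 3.37) and IGMT5 (AT1G76790, 2.02 ± 0.43, second probe 1.56) modify indole glucosinolates. STM (AT1G62360, 1.63 ± 0.45, second probe 1.99), a shoot meristem gene, was higher with them. Floral markers gave 2 higher and 0 lower among 8 measured (adjusted p = 0.706), which were AP3 (AT3G54340, 2.06 ± 0.36) and PI (AT5G20240, 1.24 ± 0.42). Of 2 meristem markers measured, STM and KNAT1 (AT4G08150, 1.33 ± 0.45, second probe 0.95) were both higher. The 8 largest rises included the anther genes AMS (AT2G16910, 4.28 ± 1.28, detected on 1 of 3 arrays of WT at 0 h), sks18 (AT1G75790, at least 8.71-fold), ACOS5 (AT1G62940, 3.93 ± 1.33) and ATA1 (AT3G42960, at least 8.57-fold). The other 4 were DIN11 (AT3G49620, 4.04 ± 1.11), LCR67 (AT1G75830, at least 4.55-fold, detected on 1 of 3 arrays of ahp4 at 0 h), CYP735A2 (AT1G67110, at least 1.91-fold, detected on 2 of 3 arrays of ahp4 at 0 h), of trans-zeatin synthesis, and BGLU22 (AT1G66280, at least 1.68-fold, detected on 2 of 3 arrays of ahp4 at 0 h).

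Cytokinin lists moved little at 0 h. Type-A response regulators gave 0 higher and 1 lower among 9 measured (adjusted p = 0.26), which was ARR17 (at least 5.85-fold, probe 16 rows from an array end). Signalling genes gave 1 higher and 1 lower among 17 measured (adjusted p = 0.706), AHP4 and the related AHP5 (AT1G03430, 1.02 ± 0.20). Metabolism gave 2 higher and 0 lower among 13 measured (adjusted p = 0.706), IPT5 (AT5G19040, 1.45 ± 0.45) and CYP735A2. Photosynthesis was the only list called by camera, with 0 higher and 1 lower among 23 measured (adjusted p = 0.0498, or 0.907 estimated, and 0.373 with quantile normalization). The lower gene was PSBO1 (-1.49 ± 0.22, n = 2 in ahp4 at 0 h, second probe -0.13, probe 11 rows from an array end). Divided by the spike-in slope, the list lay on the other side (adjusted p = 0.648). The 8 largest falls held SAR2 (at least 521-fold, probe 1 row from an array end), PAB8 (at least 253-fold, second probe 0.88, probe 2 rows from an array end) and FEI1 (at least 100.4-fold, probe 2 rows from an array end) in the outer rows. The others were PREP1 (-8.23 ± 0.56, n = 2 in ahp4 at 0 h, detected on 1 of 3 arrays of ahp4 at 0 h), GSH2 (AT5G27380, -7.69 ± 0.54, detected on 2 of 3 arrays of ahp4 at 0 h, second probe 0.14), PHO2 (AT2G33770, -7.39 ± 0.63, n = 2 in ahp4 at 0 h, second probe 0.12), ASPG1 (1 array of ahp4 at 0 h, second probe 0.16) and TUB4 (AT5G44340, -7.04 ± 0.48, n = 2 in ahp4 at 0 h, second probe 0.47), and in all 1 of 6 second probes was at least 2-fold lower. The share of higher calls, 53.4%, was 38.3% with normexp background, 67.3% with quantile normalization, 37.5% scaled to the median of bright probes and 43.4% divided by the spike-in slope. With the outermost 50 rows left out, 553 genes were higher and 306 lower. Of those with a second probe, it moved at least 2-fold the same way for 42% and 22.7%.

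At 2 h of dehydration, asked of the same 2 genotypes, the fewest genes were called. Only this genotype comparison used neither the slide of ahp4 at 0 h nor that of WT at 5 h. The counts therefore do not show at which time the genotypes differed least. No list call held with an estimated correlation. Of 20369 genes, 88 were higher in ahp4 and 90 lower. With the outermost 50 rows left out the counts were 27 and 68, and refits without replicate 3 of WT or of ahp4 gave 105 or 103 calls, against 178. In these inner rows the genes of the arabinogalactan proteins AGP13 (AT4G26320, 2.74 ± 0.56) and FLA12 (AT5G60490, 1.71 ± 0.35), the cellulase GH9C1 (AT1G48930, 1.70 ± 0.32) and the factor DREB26 (AT1G21910, 1.34 ± 0.26) were higher, chosen after their values were seen. Lower were GA20OX1 (AT4G25420, -2.82 ± 0.28, detected on 2 of 3 arrays of ahp4 at 2 h), of gibberellin synthesis, RLP28 (AT2G33080, -2.51 ± 0.49), of a receptor-like protein, and CSLB03 (AT2G32530, -2.37 ± 0.38, detected on 2 of 3 arrays of ahp4 at 2 h, second probe -2.16), of a cellulose synthase-like protein. ABCA3 (AT3G47740, at least 1.01-fold) and PP2-B2 (AT2G02250, at least 1.11-fold) were lower too. With all rows AGO5 (AT2G27880, -1.83 ± 0.41) and GLIP7 (AT5G15720, -2.53 ± 0.57, detected on 1 of 3 arrays of ahp4 at 2 h) were lower as well, but were not called with the outer rows left out (adjusted p = 0.0505 and 0.0503). The 5 loci called by 2 probes were AT3G01820 (1 array of WT at 2 h), GXM2 (AT4G09990, 1.19 ± 0.18, second probe 1.12), AT5G44410 (-1.15 ± 0.22, second probe -1.06), AT1G76530 (-1.98 ± 0.23, detected on 1 of 3 arrays of ahp4 at 2 h, second probe -1.60) and CSLB03. Of the lists, cell wall growth gave 1 higher and 0 lower among 11 measured (adjusted p = 0.0198, or 0.601 estimated, and 0.0718 with normexp background), which was XTH4 (1.29 ± 0.24). Photosynthesis, with 0 higher and 0 lower among 26 measured, 1 and 0 adjusted over the list alone, had a median 0.52 above that of all genes (adjusted p = 9.97e-05, or 0.648 estimated), and LHCB2.3 (1.58 ± 0.50) was not called. Aquaporins, with 0 higher and 0 lower among 16 measured, had a median 0.43 above it (adjusted p = 0.00109, or 0.618 estimated, and 0.0527 with normexp background). Floral markers, with 0 higher and 0 lower among 8 measured, 0 and 2 adjusted over the list alone, had a median of -0.89 against it (adjusted p = 0.00123, or 0.601 estimated), and SEP2 (AT3G02310, -1.22 ± 0.39) and AG (AT4G18960, -1.18 ± 0.48) were not called. In cytokinin signalling (1 higher and 1 lower among 17 measured; adjusted p = 0.674), ARR11 (AT1G67710, 1.03 ± 0.18), a type-B regulator, was higher and AHP4 lower. All 8 of the largest rises had a probe within 2 rows of an array end. They were PAB8 (1 array of WT at 2 h, second probe 0.46), FEI1 (5.70 ± 0.79, detected on 1 of 3 arrays of WT at 2 h), RAS1 (AT1G09950, at least 18.3-fold) and FRS7 (AT3G06250, 4.85 ± 0.59, detected on 1 of 3 arrays of WT at 2 h). The other 4 were HO3 (4.61 ± 0.70, detected on 1 of 3 arrays of WT at 2 h), SAR2 (4.60 ± 0.31), UTR6 (AT3G59360, 4.31 ± 0.59, detected on 2 of 3 arrays of WT at 2 h) and FADA (4.26 ± 0.57, detected on 1 of 3 arrays of WT at 2 h). The share of higher calls, 49.4%, was 82.9% with normexp background and 61.4% with the median of bright probes as the scale.

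The comparison at 5 h asks how the genotypes differed late in drying. No list was called downward. 652 of 20229 genes were higher and 588 lower, and 2 probes were called the same way for 14 and 35 loci. The following were chosen from these after their values were seen. EDS1 (-1.16 ± 0.36, second probe -1.31), RLP9 (AT1G58190, -2.23 ± 0.49, second probe -1.85) and PLA2A (AT2G26560, -2.25 ± 0.34, second probe -1.28) act in defence and were lower. WRKY47 (AT4G01720, -1.77 ± 0.37, second probe -1.41) was lower too. The salicylate and defence list gave 0 higher and 1 lower among 17 measured, 0 and 0 adjusted over the list alone (adjusted p = 0.524). Higher by both probes were the sulfate transporter gene SULTR1;2 (AT1G78000, 2.24 ± 0.62, second probe 2.22) and MSRB5 (AT4G04830, 1.88 ± 0.47, second probe 2.00). Type-A response regulators gave 0 higher and 3 lower among 9 measured (adjusted p = 0.227), which were ARR5 (-2.20 ± 0.47), ARR16 (-1.29 ± 0.34) and ARR17, below background in both groups. Cytokinin signalling gave 0 higher and 2 lower among 17 measured (adjusted p = 0.0532, or 0.389 estimated), AHP4 and AHP5 (-1.16 ± 0.20). That list was called with a replicate block (adjusted p = 0.0466) and in the deposited table (0.0174). In metabolism CKX4 (-1.48 ± 0.41) was lower and IPT7 (AT3G23630, 1.87 ± 0.58, detected on 1 of 3 arrays of WT at 5 h) higher, within 1 higher and 1 lower among 13 measured (adjusted p = 0.64). The receptor PYL5 (-1.20 ± 0.31), the ethylene factor gene ERF6 (AT4G17490, -1.31 ± 0.39, second probe -0.94), the clock gene PRR9 (AT2G46790, -1.29 ± 0.18) and MYBL2 (-1.51 ± 0.22) were lower.

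Protective proteins at 5 h gave 1 higher and 0 lower among 16 measured (adjusted p = 0.0282, or 0.86 estimated, 0.0593 with quantile normalization, 0.0544 with the median of bright probes, 0.276 divided by the spike-in slope and 0.208 with the outermost 50 rows left out), which was LEA4-5 (1 array of WT at 5 h). Flavonoid genes gave 0 higher and 1 lower among 19 measured, yet a median 0.80 above that of all genes (adjusted p = 0.0282, or 0.86 estimated, and 0.068 with the median of bright probes), and the lower gene was MYBL2. Largest falls further held EDA36 (AT4G13890, at least 3.85-fold), CRK23 (-2.71 ± 0.80, detected on 1 of 3 arrays of ahp4 at 5 h), the iron factor gene BHLH101 (AT5G04150, -2.59 ± 0.76, detected on 2 of 3 arrays of ahp4 at 5 h) and PIF4 (AT2G43010, -2.18 ± 0.21), a factor of light signalling. Of the 8 largest rises, 6 lay within 50 rows of an end, and 1 of 4 second probes rose 2-fold. They were BZIP53 (1 array of WT at 5 h, second probe -0.60, probe 7 rows from an array end), ASPG1 (1 array of WT at 5 h, second probe 0.09), SVB (1 array of WT at 5 h, second probe -0.14) and SUS2 (1 array of WT at 5 h, second probe 3.01, probe 14 rows from an array end). The 4 without a second probe were ARD1 (8.25 ± 0.23, n = 2 in WT at 5 h), RPL34 (7.24 ± 0.99, n = 2 in WT at 5 h, detected on 2 of 3 arrays of WT at 5 h, probe 8 rows from an array end), SAR2 (at least 133-fold, probe 1 row from an array end) and U1-70K (AT3G50670, 6.46 ± 0.91, detected on 1 of 3 arrays of WT at 5 h, probe 4 rows from an array end). 315 genes were lower in ahp4 at 0 h and higher at 5 h, against 24.3 for independent lists, and 77.1% of them lay within 20 rows of an end, as did 6.05% of all genes. 125 were higher at 0 h and lower at 5 h, against 27, with 14.4% within 20 rows. Their median signal was 0.65 in ahp4 at 0 h and 0.68 in WT at 5 h, and -0.71 to -0.33 in the other groups. AHP5, which has no second probe, and ASL9 were among them. The share of higher calls at 5 h, 52.6%, was 78.9% with normexp background, 40.3% with quantile normalization, 69.4% with the median of bright probes and 64.9% in the deposited value table. With the outermost 50 rows left out, 174 were higher and 286 lower. Of those with a second probe, it moved at least 2-fold the same way for 25.9% and 37.8%.

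The last comparisons test whether ahp4 responded to dehydration differently from WT. At 2 h the response differed for 1404 of 20285 genes, more positive in ahp4 for 461 and more negative for 943. Second probes moved 2-fold the same way for 22.9% and 19.7% of the 96 and 304 called loci that had one. Genes called by both probes, chosen after their values were seen, lay mostly on the negative side. They were the glucosinolate genes CYP81F4 (-3.46 ± 0.63, second probe -4.24) and IGMT5 (-2.10 ± 0.60, second probe -1.85), and the flavonoid hydroxylase gene TT7 (-1.94 ± 0.60, second probe -1.85). With them went the anther regulator TGA9 (AT1G08320, -2.33 ± 0.64, second probe -2.28), detected on 2 of 3 arrays of ahp4 at 2 h, and the floral gene AG (-2.34 ± 0.67, second probe -2.18). Floral markers gave 0 upward and 4 downward among 8 measured (adjusted p = 0.108), with AP3 (-3.11 ± 0.51), PI (-2.23 ± 0.59) and SEP2 (-2.21 ± 0.55). Photosynthesis gave 2 upward and 0 downward among 23 measured (adjusted p = 3.4e-06, or 0.79 estimated, and 0.225 divided by the spike-in slope), which were LHCA4 (1 array of ahp4 at 0 h, second probe 0.34) and PSBO1 (1.83 ± 0.32, n = 2 in ahp4 at 0 h, n = 2 in WT at 2 h, second probe 0.66, probe 11 rows from an array end). The largest differences were upward for PAB8, SAR2, FEI1, Cand6, HO3, FRS7, ECIP1 (AT4G24800) and UTR6, all with a probe within 2 rows of an end. Downward they included ACOS5, AMS and sks18, the last 2 detected on at most 1 of 3 arrays of ahp4 at 2 h and WT at 0 h. The share of upward differences, 32.8%, was 60.8% with normexp background, 20% with quantile normalization, 55% with the median of bright probes as the scale and 45.2% in the deposited value table. The median of all genes was -0.24, and -0.04 on that scale.

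At 5 h the response differed for 3678 of 20176 genes, 968 upward and 2710 downward in ahp4. No list was called by camera. By both probes, and chosen after their values were seen, the response was more negative for PLA2A (-3.17 ± 0.49, second probe -1.86), RLP9 (-2.83 ± 0.69, second probe -2.39) and WRKY47 (-2.51 ± 0.52, second probe -1.95). The salicylate and defence list gave 0 upward and 0 downward among 17 measured (adjusted p = 0.698). The glucosinolate gene CYP81F4 (-3.03 ± 0.63, second probe -4.15), the lateral organ gene ASL9 (AT1G16530, -3.13 ± 0.54, second probe -2.40) and the abscisic acid hydroxylase gene CYP707A1 (-1.28 ± 0.40, second probe -1.39) lay downward too. SULTR1;2 (3.01 ± 0.88, second probe 2.84) lay upward. Cytokinin signalling gave 0 upward and 5 downward among 17 measured (adjusted p = 0.33), which were AHP5 (-2.18 ± 0.28), AHK2 (-1.60 ± 0.23), CRF6 (AT3G61630, -1.79 ± 0.25), CRF5 (-1.09 ± 0.31, probe 11 rows from an array end) and ARR12 (AT2G25180, -1.42 ± 0.21, second probe -0.59). CRF5 was named after its value was seen, and its difference was 0.96 with normexp background (adjusted p = 0.0171). Type-A regulators gave 0 upward and 1 downward among 9 measured (adjusted p = 0.891), which was ARR5 (-2.69 ± 0.66). Abscisic acid receptors gave 0 upward and 2 downward among 9 measured (adjusted p = 0.698), which were PYL5 (-1.77 ± 0.43) and PYL2 (-1.42 ± 0.29). The largest upward differences were those of ASPG1, SAR2, PAB8, RBP45B (AT1G11650), U1-70K, SCL5 (AT1G50600), BAM2 (AT4G00490) and ECIP1, of which 7 lay within 50 rows of an end and 0 of 3 second probes moved 2-fold the same way. The share of upward differences, 26.3%, was 44.8% with the median of bright probes as the scale and 38.9% in the deposited value table. The median of all genes was -0.33 and -0.04 in turn.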

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

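The response to dehydration differed between genotypes by the interaction test for 1404 genes at 2 h and 3678 genes at 5 h. Differences below are those of named genes, many chosen after their values were seen. At 2 h the floral genes AP3 (-3.11 ± 0.51), AG (-2.34 ± 0.67), PI (-2.23 ± 0.59) and SEP2 (-2.21 ± 0.55) were downward. So was the anther regulator TGA9 (-2.33 ± 0.64), detected on 2 of 3 arrays of ahp4 at 2 h. AP3 and PI were higher in ahp4 at 0 h and rose in WT at 2 h. Whether tissue content differed between samples was not tested. CYP81F4 (-3.46 ± 0.63), IGMT5 (-2.10 ± 0.60) and TT7 (-1.94 ± 0.60) lay downward too. AHP5 (-1.10 ± 0.28) and ELF3 (AT2G25930, -1.19 ± 0.27, n = 2 in ahp4 at 0 h) were smaller differences on the same side. Upward were EXPA1 (1.52 ± 0.43) and XTH4 (1.16 ± 0.34, second probe 0.92), and PSBO1 (1.83 ± 0.32, n = 2 in ahp4 at 0 h, n = 2 in WT at 2 h, second probe 0.66, probe 11 rows from an array end) of photosynthesis.

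At 5 h the cytokinin genes AHP5 (-2.18 ± 0.28), a paralogue of AHP4, AHK2 (-1.60 ± 0.23) and ARR5 (-2.69 ± 0.66) were downward. CRF6 (-1.79 ± 0.25), ARR12 (-1.42 ± 0.21, second probe -0.59) and CRF5 (-1.09 ± 0.31, probe 11 rows from an array end) followed, but CRF5 was upward with normexp background (0.96, adjusted p = 0.0171). The abscisic acid genes PYL5 (-1.77 ± 0.43), PYL2 (-1.42 ± 0.29) and CYP707A1 (-1.28 ± 0.40) lay downward, as did PLA2A (-3.17 ± 0.49), RLP9 (-2.83 ± 0.69) and WRKY47 (-2.51 ± 0.52). Also downward were ASL9 (-3.13 ± 0.54), CYP81F4 (-3.03 ± 0.63), MYBL2 (-2.01 ± 0.31), SDD1 (AT1G04110, -2.05 ± 0.53) and PDF1.3 (-6.07 ± 2.10). SULTR1;2 (3.01 ± 0.88) was upward. AHP5 and ASL9 were among the genes higher at 0 h and lower at 5 h in ahp4, whose median was raised on the slides of ahp4 at 0 h and WT at 5 h, and AHP5 has no second probe. Both counts hang on the 0 h slide of ahp4, the 2 h count also on the 2 h slide of WT and the 5 h count on the 5 h slide of WT. Second probes moved at least 2-fold the same way for 25.4% of the upward and 23.9% of the downward genes at 5 h that had one.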

How the results depend on the processing

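In the order ahp4 against WT at 0, 2 and 5 h, WT at 2 against 0, 5 against 0 and 5 against 2 h, the same for ahp4, and the genotype difference at 2 and 5 h, the counts of called genes were 1745, 178, 1240, 4329, 6918, 4152, 6436, 7155, 3276, 1404 and 3678. The 6 dehydration counts stayed within 1.5 times of these under every alternative except 2. With no fold limit the 11 counts were 4908, 311, 3145, 7726, 10939, 7913, 10610, 11174, 6315, 2597 and 5965, since smaller changes then count. Called by 2 probes of a locus, which fewer loci have, they were 65, 5, 49, 876, 1165, 581, 1111, 1385, 668, 43 and 206. Counts between genotypes moved more. With no filter on dim probes, when more genes are tested, they were 3372, 1099 and 2084 at 0, 2 and 5 h and 5618 for the difference at 5 h. With probes well above background on all arrays, when fewer are, they were 1018, 28 and 711, and 931 for the difference at 2 h. With the outermost 50 rows left out they were 859, 95 and 460, and 558 and 2207 for the differences. Only the compared groups in the fit gave 102 at 2 h and 746 at 5 h, and with the local position trend removed 5 h gave 784 and the 2 h difference 887. At 2 h, array weights gave 424 and leaving the slides of WT 5 h and ahp4 0 h out of the fit gave 391 (169 higher, 222 lower). The difference at 2 h was 2238 with quantile normalization and 862 with the median of bright probes as the scale, and that at 5 h 6639 with normexp background. Where no reason is given, the cause was not tested.

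With each array left out in turn the 11 counts ranged over 1172 to 2373, 103 to 182, 898 to 1420, 3897 to 4153, 6489 to 7084, 3724 to 4447, 6022 to 6894, 6416 to 7687, 2697 to 3181, 999 to 1854, 3229 to 4196. AHP4 in ahp4 against WT ranged over -4.89 to -4.39, -5.96 to -4.05, -4.24 to -3.65 at 0, 2 and 5 h and stayed called, as under every scaling except normexp background (-1.49 at 2 h and -0.78 at 5 h). That correction with its offset narrows the low end, where AHP4 lies in ahp4.

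Of 405 gene values in the text, normexp background ended 42 calls, fits of the compared groups alone 35, array weights 34, the median of bright probes 28, the values as deposited 21, the spike-in slope 24, the position trend 21, the mean of all probes 11, a replicate block 9, quantile normalization 7 and trend and robust eBayes 2. Array weights added 2. Calls were lost for 29 of 147 values with 2 probes, 16 of 353 with the outermost 50 rows left out, 2 of 361 without outlier-marked loci, 1 of 287 well above background on all arrays and 251 of 2616 refits without an array. With the outermost 50 rows left out another probe stands for PAB8 (0.88 between genotypes at 0 h). CRF5 turned to 0.96 in the 5 h difference with normexp background, and the cause was not tested. Of 104 list results, 60 calls were lost with an estimated correlation, 9 with fry, 6 with normexp background, 5 with quantile normalization, 5 with the spike-in slope, 3 in the deposited table, 2 with the median of bright probes, 2 with the position trend removed, 2 with the outermost 50 rows left out and 1 with a replicate block. Except for fry, their p-values stand beside the results. Photosynthesis at 0 h turned (median 0.27) when divided by the spike-in slope, and the cause was not tested. Fry, which tests a list against no change and not against other genes, gained 20 calls. Lists gained otherwise, besides cytokinin signalling at 5 h as given above, were cell wall growth in WT at 5 h with normexp background (adjusted p = 0.0276) and quantile normalization (0.0319), guard cells in ahp4 at 2 h with quantile normalization (0.0346) and in the deposited table (0.0469), reference genes in WT at 5 h with the spike-in slope (0.0434) and floral markers in the 2 h difference with the median of bright probes (0.0174), in the deposited table (0.0252) and with the outermost 50 rows left out (0.0451).

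The replicate numbers were not taken as pairs. Deviations of arrays with the same number correlated at -0.30 to 0.18 across genes, over 0.1 in 12 of 45 pairs, and over 0.1 in 12 of 90 pairs with different numbers. The medians were -0.01 and 0.00. With the number as a replicate block the 11 counts were 1651, 141, 1157, 4270, 6872, 4094, 6411, 7091, 3229, 1313 and 3577. A block for scan day or scanner was planned but not run, because each scan day held 1 genotype and could not be fitted. Where a probe was not well above background in a group, only a bound can be given, and the size of a change there is limited by the background.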

Other observations

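Ethylene genes gave 2 rises and 2 falls among 12 measured in WT at 5 h (adjusted p = 0.89) and 3 rises and 2 falls among 12 measured in ahp4 (adjusted p = 0.462). The synthase gene ACS2 (AT1G01480) rose in both, 7.20 ± 0.98 and 7.85 ± 0.98. The oxidase gene ACO1 (AT2G19590, -2.11 ± 0.50) fell in ahp4. Guard cell genes gave 2 rises and 4 falls among 14 measured in WT at 5 h (adjusted p = 0.553). MYB60 (AT1G08810, -2.39 ± 0.24), which promotes opening, and the kinase gene HT1 (AT1G62400, -1.44 ± 0.13) fell, and the outward potassium channel gene GORK (AT5G37500, 2.29 ± 0.20) rose. The list median there was 0.26 and its mean -0.04, and the test pointed down.

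Clock genes gave 3 rises and 2 falls among 16 measured in WT at 5 h (adjusted p = 0.896) and 3 rises and 5 falls among 16 measured in ahp4 (adjusted p = 0.957), with the evening gene ELF4 (AT2G40080) at 2.36 ± 0.20 and 2.13 ± 0.20. Floral genes gave 3 rises and 0 falls among 8 measured in WT at 2 h (adjusted p = 0.109), which were AP3 (1.34 ± 0.36), PI (1.20 ± 0.42) and SEP2 (1.41 ± 0.39), and 0 rises and 2 falls among 8 measured in ahp4 (adjusted p = 0.447), which were AP3 (-1.77 ± 0.36) and AG (-1.66 ± 0.48). Reference genes gave 2 rises and 0 falls among 8 measured in WT at 5 h (adjusted p = 0.174), which were UBC21 (AT5G25760, 1.00 ± 0.12) and SAND (AT2G28390, 1.37 ± 0.09), and 1 rise and 1 fall among 8 measured in ahp4 (adjusted p = 0.241), UBQ10 (AT4G05320, 1.14 ± 0.26) and ACT2 (AT3G18780, -1.57 ± 0.14).

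Of the tests below, those of the outer rows and of AHP4 against its neighbours were chosen after the results were seen, the others before. Genes called lower at 0 h in ahp4 and at 5 h in WT could reflect signal lost at places of the slides or lower transcript. Second probes, where present, fell at least 2-fold for 21.7% of genes lower in ahp4 at 0 h, 67.9% in WT at 5 h against 0 h and 53% against 2 h. Where neither slide was used, in ahp4 at 5 h against 2 h, the share was 88.4%. For genes higher in ahp4 at 0 h it was 25.6%, against 85.9% among rises there. Of the genes lower at 0 h and higher at 5 h in ahp4, 77.1% lay within 20 rows of an end, so loss of signal along these rows fits most of them, and a change of transcript remains open for genes that 2 probes call. The 125 genes higher at 0 h and lower at 5 h, of which 14.4% lay there, had a raised median on the same 2 slides, and what raised it remains open.

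AHP4 could be low in ahp4 because the outer rows lost signal there or because the mutant holds less transcript. Of other genes within 10 rows of an end, 14.1% were as low or lower at 0 h, 0 of 567 at 2 h and 0 of 544 at 5 h. The outer rows could account for part of the value at 0 h, and not for those at 2 and 5 h. Where the insertion lies against the probe is not given, so whether a shortened transcript remains is open.

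Clock genes may have moved with the hour of sampling, with detachment or with dehydration. They were called in 18.8% and 31.2% of cases in WT at 2 and 5 h, against 21.3% and 34.2% of all genes. In ahp4 the shares were 43.8% and 50%, against 31.7% and 35.2%. With 16 clock genes these shares do not separate the explanations.

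With no fold limit 79.2% of genes called at 0 h were higher in ahp4, and 73.3% after each array was divided by its spike-in slope. Each 3 against 3 comparison has 10 splits of its arrays, too few for a share under 0.05, and the real grouping was the only 1 of 10 to give as many calls as it did. The most calls in another split were 3, 1 and 1 between genotypes at 0, 2 and 5 h, 0, 0 and 20 in WT (2 h and 5 h against 0 h, 5 h against 2 h) and 1, 2 and 1 in ahp4. For the genotype differences, only the real grouping of 100 seeded splits reached its count, and the others gave at most 934 at 2 h and 802 at 5 h.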
